A study of Drosophila melanogaster with 4 samples.

How the data were processed

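Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 monomethylated at lysine 4 (H3K4me1), a mark commonly found at enhancers and beside promoters, in wandering third-instar larvae of the Y cn bw sp strain of Drosophila melanogaster. Per the labels' protocols, larvae were cross-linked with formaldehyde and chromatin was precipitated with an affinity-purified polyclonal rabbit antibody. The series holds 4 samples, of which 2 are H3K4me1 ChIP libraries and 2 are input DNA libraries, the DNA of the same kind of chromatin without the antibody step. The labels do not say whether the 2 samples of a group came from separate collections of larvae.

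The deposited data analysed here are 1 list of peaks for the whole series. Per the file headers, its positions are in FlyBase release 5 coordinates and its source is MACS. The submitters' processing notes name CASAVA versions 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5. Peak-calling settings, the peak threshold, the treatment of duplicate and multiply aligned reads, and the way the 2 ChIP and 2 input samples were combined are not given in the sources used here. Each peak has a start, an end and a score that the authors' peak caller gave it as deposited. The scale of that score is not stated, so it was used only to describe, rank, filter and compare peaks within the list. Ratios of scores have no set meaning on an unknown scale. The list gives no read counts, no value per sample and no summit position, so the sequencing depth is unknown and no error between replicates can be given. Peak numbers ran without a break from 1 to 14326, and no other column of sample values was present.

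Starts were read as counted from 0, because 2 peaks start at 0 and the smallest difference between end and start is exactly 200 bp. Positions below are counted from 1. Widths are end minus start.

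Coverage was measured in bins of 1 Mb on the arms 2L, 2R, 3L, 3R and X, counted from the centromere end of each arm and lying between its first and last peak, since no sequence of the build was used here. A last bin shorter than 50% of the bin size was left out. X bins were compared with autosomal bins, and the 5 bins nearest the centromere with the other bins of the same arms, by two-sided permutation tests on the mean covered share with 100000 resamples. Intervals are 95% bootstrap intervals over bins from 10000 draws. Widths and scores of peaks on X and on the autosomal arms were compared by 2000 bootstrap draws of whole 1 Mb blocks. Gaps between neighbouring peaks were compared with 1000 random placements of the same peaks without overlap on each arm. Score and width were related across peaks by Spearman's rho with 100000 permutations. These 4 tests form a family, and Benjamini-Hochberg adjusted values are given over it. All p-values compare bins or peaks within a single list and say nothing of the spread between samples. Neighbouring bins were correlated (r = 0.28 over 112 pairs of adjacent bins), which makes the bin p-values too small.

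The bin test was tested on simulated data made by shuffling the real bins across the arms. Without an effect it gave a p below 0.05 in 14 of 200 simulations (7%), and with 5 percentage points added to X in 162 of 200 (81%). Shuffling removes the correlation between neighbouring bins and the differences between arms, so these rates cover neither. The 5 points added are more than the difference of 3.36 points found in the list. The spacing test gave such a p in 4 of 60 simulations of randomly placed peaks and in 60 of 60 with clusters added. The random peaks were placed by the same rule as the test's own placements. The spacing rates therefore cover neither uneven peak density nor splitting of regions by the caller.

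The 10 peaks with the highest score and the 10 widest are named by a rule written before the data were examined. The peak on YHet, the outermost peaks of the arms, the longest joined regions, the peak-free stretches and the single bins were chosen after their values were seen. Added after the data were examined were X against the autosomes without each autosomal arm in turn and without the 2 bins nearest each centromere, the nearest 2 bins, the nearest 6 bins and bins 3 to 5 in the centromere comparison, random placement within 1 Mb bins and with the smallest gap of the list, and the tests of the closing section except the score and 500 bp merging alternatives. The block comparison of widths and scores on X and the same-length windows for chromosome 4 were not in the plan written before the data were examined. The other tests and alternatives were fixed before. The alternatives were the upper 50% and the upper 25% of scores, bins of 500 kb and 2 Mb (the latter with 3 bins, or 6 Mb, next to each centromere in place of 5 Mb), peaks per Mb in place of covered share, other gap limits, peaks merged across gaps of 500 bp or less, and the large arms alone. Planned comparisons with genes, transcription start sites, exons and introns, including 19 gene lists, were not run, because the gene table used here is of another assembly (Release 6) and positions were not converted between builds. Positions are therefore given without gene names.

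Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.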

Results

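The peak list of this series of 2 H3K4me1 ChIP and 2 input samples held 14326 regions called in chromatin of larvae at the wandering third-instar stage. Together the peaks covered 21.8 Mb. The large arms 2L, 2R, 3L, 3R and X held 14009 of them, chromosome 4 held 145, and the heterochromatic and unplaced scaffolds held 172. The median peak was 823 bp wide, with quartiles of 389 and 1804 bp and a range from 200 bp to 37.1 kb. Peaks under 500 bp made up 33.4% of the list and 7.07% of the covered sequence, whereas the 754 peaks of 5 kb or wider made up 5.26% of the list and 28.4% of the covered sequence. The peak caller's score had a median of 32.9, with quartiles of 16.9 and 79.1 and a range from 5.98 to 527. The list has no replicates, and no error below is a spread between samples.

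Positions are in FlyBase release 5 coordinates. Of the 10 peaks with the highest score, 5 were on X, 2 each on 3L and 3R, and 1 on 2R. The top peak was at X, 2178975 to 2203378, 24.4 kb wide, with a score of 527. It was followed by X, 3662500 to 3674858 (score 488), and X, 12636299 to 12657601 (score 481). The best-scoring autosomal peak, at 3R, 4878378 to 4883592, had a score of 468 and was 5.22 kb wide. The other X peaks in this group were at 9470093 to 9479801, with a score of 467, and at 1902028 to 1906378, with a score of 436. The remaining autosomal peaks were at 3L, 10657950 to 10678945, at 3R, 12031230 to 12039578, at 2R, 3413953 to 3420706, and at 3L, 14751118 to 14755051, with scores between 424 and 428.

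The 3 widest regions lay on 2R. A peak at 2R, 7061306 to 7098390, spanned 37.1 kb without interruption, and others at 2R, 7478843 to 7506466, and 2R, 8904169 to 8930779, spanned 27.6 and 26.6 kb. X held 4 of the 10 widest peaks. A pair of them, at 12611588 to 12635551 and 12636299 to 12657601, stood side by side, and another at 12553489 to 12574209 lay on the same stretch of X. The list of the widest was completed by X, 2178975 to 2203378, 2L, 476576 to 499866, 3L, 10657950 to 10678945, and 3L, 1 to 21096, which begins at the first base of the arm. Only 3 peaks belonged to both groups of 10. The widest peak ranked 322 by score.

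Score and width rose together across peaks. Spearman's rho was 0.88 over all 14326 peaks (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4e-05), and between 0.83 and 0.90 within each of the large arms, chromosome 4 and the unplaced scaffold Uextra. Peaks are not independent replicates. Score and width were also both given by the same peak caller, so the p does not test a relation apart from peak calling. Among the upper 25% of scores, where the range of scores is narrower by construction, rho was 0.41.

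The X chromosome was compared with the autosomal arms for its share of sequence under peaks. Peaks covered 21.2% ± 7.62 of X bins (SD, n = 22 bins) and 17.8% ± 6.98 of autosomal bins (SD, n = 95 bins). The difference of 3.36 percentage points (95% interval -0.016 to 6.77) was near the threshold of the permutation test (p = 0.048, adjusted p = 0.048), while the bootstrap interval reached 0. Peaks on X were not denser. X had 113 ± 34.3 peaks per Mb (SD, n = 22 bins), against 121 ± 39.3 on the autosomal arms (SD, n = 95 bins; permutation p = 0.41, 95% interval of the difference -24.1 to 8.11). In comparisons of width and score outside the written plan, the peaks on X were wider. Their median width was 968 bp against 819 bp on the autosomal arms, a ratio of 1.18 (95% interval 1.07 to 1.38). The upper quartile of width was 2329 bp on X and 1717 bp on the autosomal arms, a ratio of 1.36 (95% interval 1.24 to 1.51). Peaks of 5 kb or wider made up 7.67% of X peaks and 4.86% of autosomal peaks, a ratio of 1.58 (95% interval 1.29 to 1.92). The median score was 36.5 on X and 32.5 on the autosomal arms, a ratio of 1.12 (95% interval 1.00 to 1.27), and the lower quartiles were 16.7 and 17.0. The upper quartile of score was 98.5 on X and 75.1 on the autosomal arms, a ratio of 1.31 (95% interval 1.18 to 1.49). The scale of the score is unknown, so the score ratios give a direction and not a fold difference in signal.

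**Figure D1:**
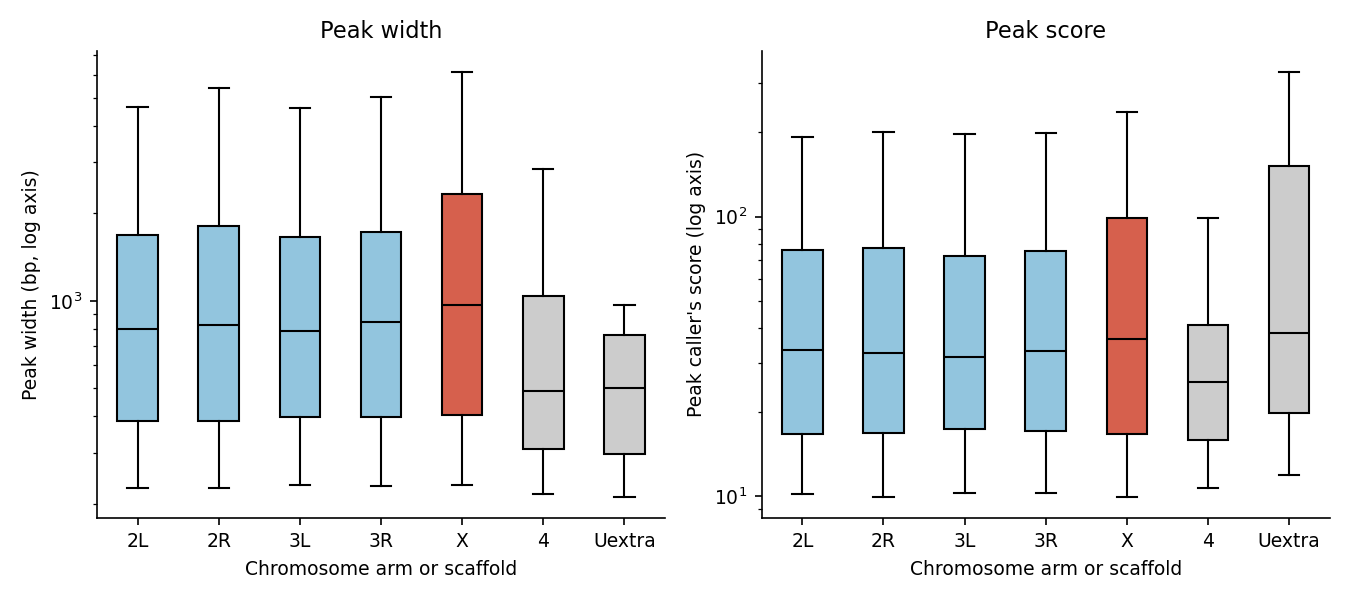
Peak width in bp (left, log axis) and the peak caller's score (right, log axis) for the 5 large arms, chromosome 4 and Uextra. Boxes show the quartiles and the median over peaks, and whiskers the 5th and 95th percentiles. X has the highest upper quartile of width, 2329 bp, and chromosome 4 has the lowest median width, 491 bp.

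The difference in coverage was 3.36 percentage points in the full list, 3.72 in the upper 50% of scores and 4.22 in the upper 25%. In the upper 25%, peaks covered 14.7% ± 6.24 of X bins (SD, n = 22 bins) and 10.4% ± 4.93 of autosomal bins (SD, n = 95 bins), with a 95% interval of the difference from 1.53 to 6.998 (permutation p = 0.0008). The autosomal arms also differed among themselves. Mean coverage was 15.2% on 2L, 20.8% on 2R, 18.0% on 3L and 17.6% on 3R, so that 2R lay close to X. With 1 X and 4 autosomal arms, an exact test over arms cannot give a p below 0.2. Without 2L the difference was 2.52 percentage points (permutation p = 0.13), and without 3L or 3R it was 3.42 and 3.28 (permutation p = 0.055 and 0.082), whereas without 2R it was 4.20 (permutation p = 0.015). Without the 2 bins nearest each centromere it was 4.15 (permutation p = 0.013). These alternatives were added after seeing the data.

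**Figure D2:**
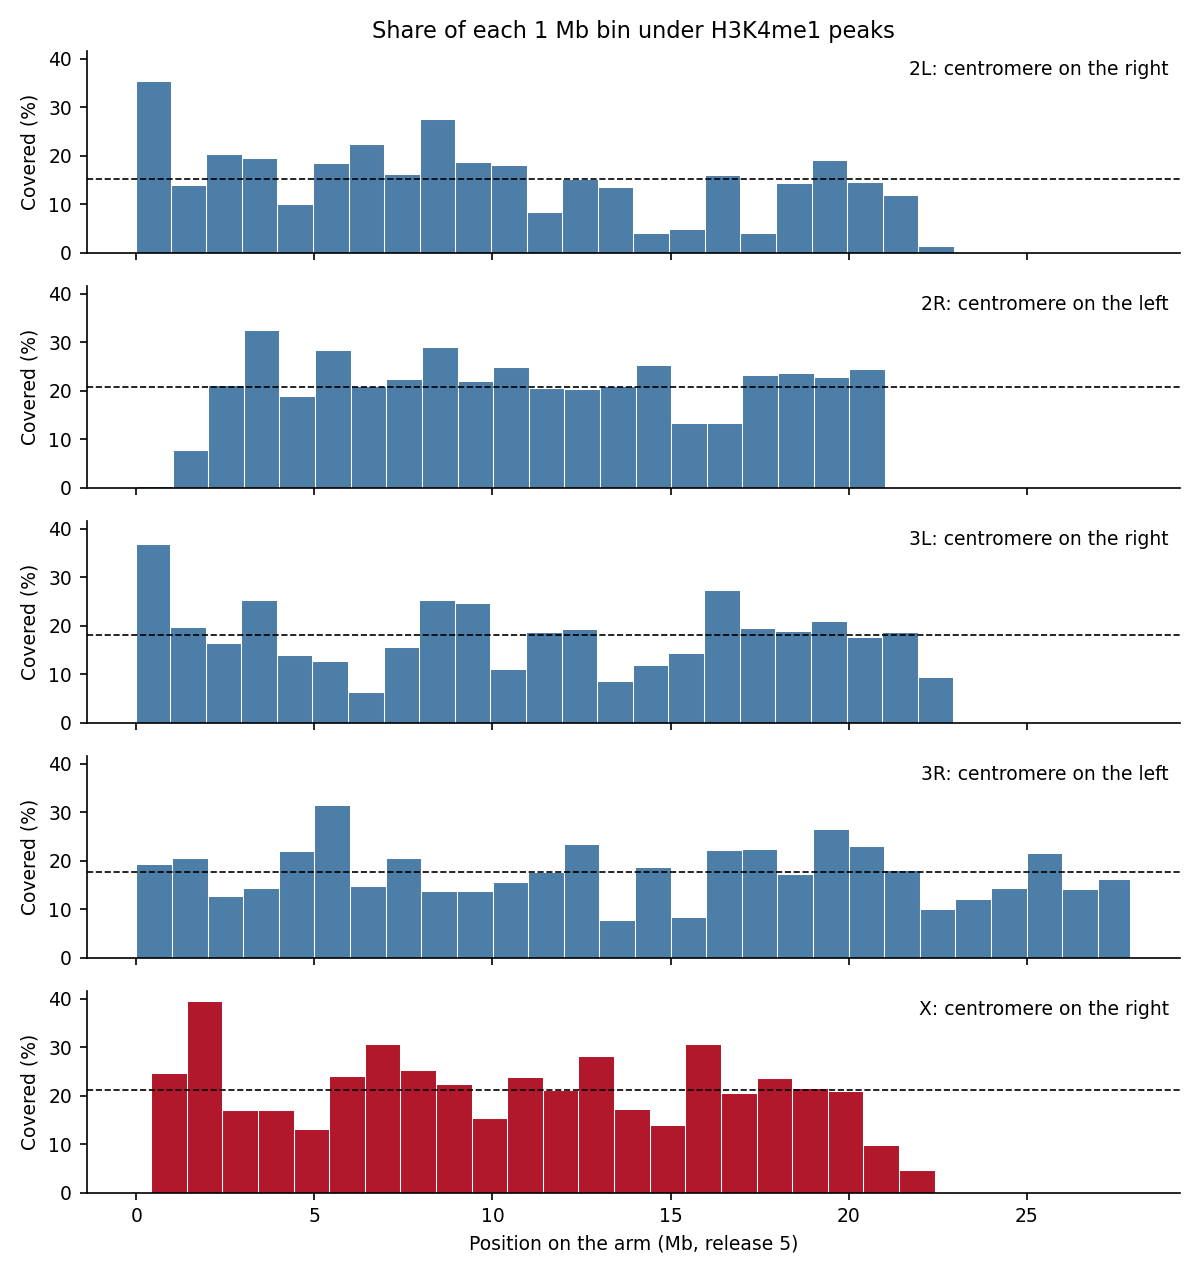
Share of each 1 Mb bin covered by peaks (vertical axis, percent) against position on the arm (horizontal axis, Mb). The dashed line is the mean over the bins of an arm, from 15.2% on 2L to 21.2% on X. The bins next to the centromere are low on 2L, 2R, 3L and X.

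Sequence next to the centromere had less of its length under peaks on 4 of the 5 large arms. The bin next to the centromere was covered by peaks to 0.426% on 2R, 1.46% on 2L, 4.64% on X and 9.52% on 3L, all below the mean of their arm. On 3R it was covered to 19.3%, above the arm's mean of 17.6%. Covered share was taken over the whole bin, and the treatment of multiply aligned reads is not known. Sequence without the mark therefore cannot be told apart from sequence where reads could not be placed. Over the 5 bins nearest each centromere, coverage was 15.9% ± 7.39 (SD, n = 25 bins), against 19.1% ± 7.03 in the other bins (SD, n = 92 bins). The difference was -3.19 percentage points (95% interval -6.30 to -0.052, permutation p = 0.045 within arms, adjusted p = 0.048). In peaks per Mb it was -11.6 (95% interval -31.2 to 7.42, permutation p = 0.18). The nearest 2 bins held 10.4% ± 7.27 (SD, n = 10 bins) against 19.2% ± 6.75 elsewhere (SD, n = 107 bins). This split and that of bins 3 to 5 were chosen after the low bins were seen, so the first split's permutation p of 0.00014 does not count as a test. The second bin of 3L, with 18.8%, and that of 3R, with 20.6%, lay above the mean of their arm. Bins 3 to 5 held 19.6% ± 4.85 (SD, n = 15 bins), a difference from the distal bins of 0.48 percentage points (95% interval -2.15 to 3.35). The alternative with bins of 2 Mb took 6 Mb of each arm in place of 5 Mb and missed the threshold (-1.90 percentage points, permutation p = 0.23). The nearest 6 bins of 1 Mb, a comparison added after seeing the data, missed it as well (-2.28 percentage points, 95% interval -5.48 to 0.86, permutation p = 0.13).

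Among single bins, the most covered was X, 1416041 to 2416040, with 39.6% of its sequence under peaks and 167 peaks per Mb. It contains the peak with the highest score. The outermost bins of 3L (1 to 942990) and 2L (1 to 960330) followed with 36.9% and 35.3%. The bins with the least coverage away from the centromeres were on 2L. The bin 16960331 to 17960330 had 4.01%, and 13960331 to 14960330 had 4.08%.

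Chromosome 4, a small autosome that is largely heterochromatic, had narrower and lower-scoring peaks than the large arms. It held 113 peaks per Mb over 1.28 Mb, against 119 on the large arms together. Its median width was 491 bp (95% interval of the median 406 to 619), against 839 bp on the large arms (818 to 862). Its median score was 25.5 (95% interval 20.3 to 27.5), against 33.1 (32.3 to 34.0). Peaks covered 10.1% of chromosome 4 and 18.4% of the large arms, a ratio of 0.55, and the ratio was 0.34 in the upper 25% of scores. Of 1112 windows of the same length on the large arms, taken every 100 kb and overlapping, 9.17% had lower coverage and 39.1% had fewer peaks. These intervals treat peaks as independent, and the comparison of a single chromosome has no test.

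By count, the assembled heterochromatic scaffolds held few peaks. Their lengths were not used here, so no density of peaks can be given for them. There were 6 on XHet and 1 each on 3LHet and YHet, and no other heterochromatic scaffold appeared in the list. The peak on YHet, at 306601 to 306841, singled out after its values were seen, was 241 bp wide with a score of 21.8. The unplaced scaffold U held 18 peaks. Uextra, which gathers unplaced pieces of the assembly, held 146 peaks with a median width of 503 bp, a median score of 38.1 and an upper quartile of score of 152, against an upper quartile of 79.3 on the large arms. The list gives no input reads for these scaffolds.

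**Figure D3:**
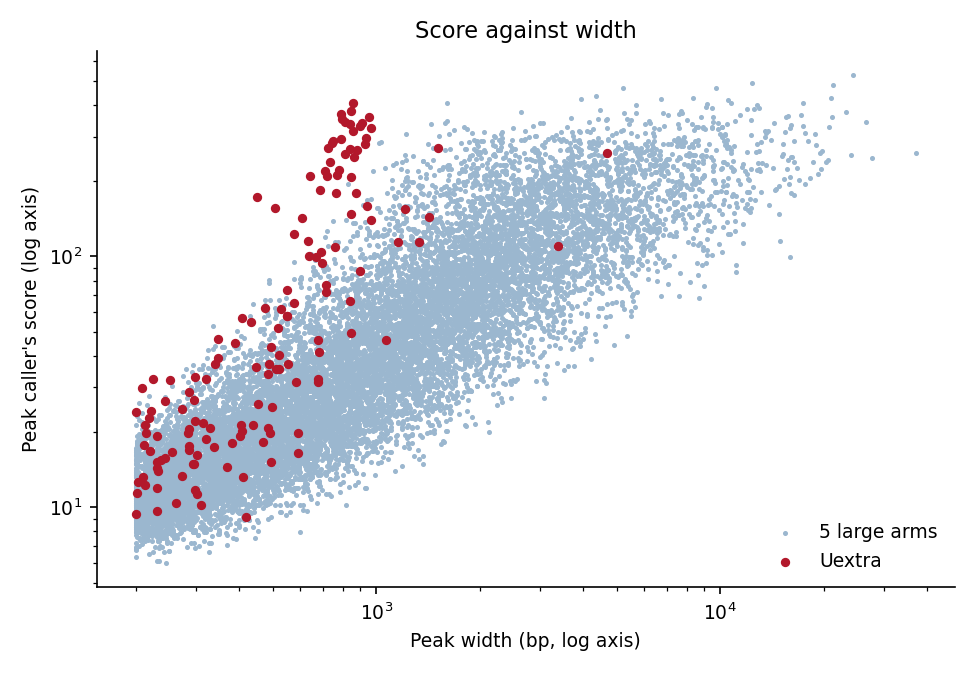
The peak caller's score (vertical log axis) against peak width in bp (horizontal log axis), 1 point per peak, for the 5 large arms and for Uextra. A group of Uextra peaks under 1000 bp wide lies above the peaks of the large arms at the same width, up to a score of 407.

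Peaks came in groups. On the large arms 8583 of the 14004 gaps between neighbouring peaks (61.3%) were 1 kb or shorter, against 13.7% ± 0.27 (SD over 1000 placements) when the same peaks were placed at random (permutation p = 0.001, the smallest that these placements can give, adjusted p = 0.002). The median gap was 656 bp and the smallest was 51 bp. Joined across gaps of 1 kb or less, the peaks formed 5426 regions with a median width of 2.44 kb and quartiles of 0.913 and 5.89 kb. Of these, 2156 consisted of a single peak and 766 of at least 5 peaks. The longest region, at 2R, 8852319 to 8930779, was 78.5 kb long with 9 peaks. It was followed by 3R, 12026015 to 12085457 (59.4 kb, 10 peaks), and 2L, 476576 to 533525 (57.0 kb, 8 peaks).

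**Figure D4:**
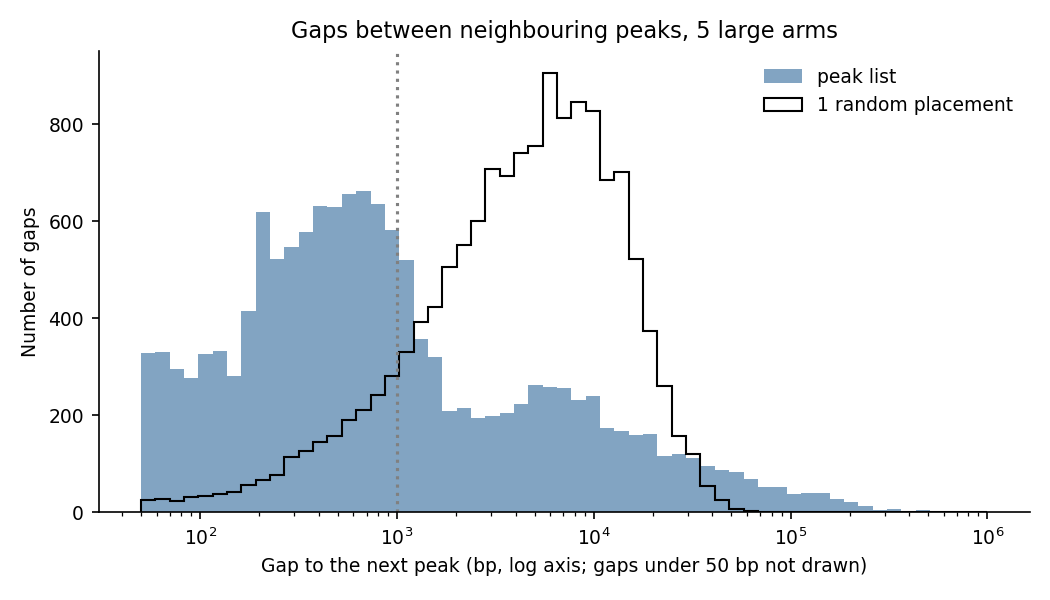
Number of gaps (vertical axis) by the length of the gap to the next peak in bp (horizontal log axis) on the 5 large arms, for the peak list (filled) and for 1 random placement of the same peaks (line). The dotted line marks 1 kb, at or below which 61.3% of the gaps in the list fall.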

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

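Of the 41 alternative values, 24 kept their direction and their side of the threshold or stayed within their error. No paired analysis was possible because the single peak list gives no value per sample, and for the same reason no replicate could be left out. Neighbour spacing (excess of 28.2 to 48.1 percentage points) and the relation of score to width (rho of 0.41 to 0.89) held under every alternative run; the 48.1, from placements with the smallest gap of the list, was added after seeing the data. For X against the autosomes, peaks per Mb reversed the sign (-7.50 peaks per Mb). Alternatives that left out an arm or bins were added after seeing the data. The difference in covered share missed the threshold without 2L (2.52 percentage points, permutation p = 0.13). It also missed it without 3L (3.42, permutation p = 0.055) and without 3R (3.28, permutation p = 0.082). Without 2R it passed (4.20, permutation p = 0.015), as it did without the 2 bins nearest each centromere (4.15, permutation p = 0.013). Without 3L or 3R the difference stayed close to the 3.36 of the full list, while the autosomal bins fell from 95 to 72 and 67. Of the autosomal arms, 2L had the lowest mean coverage (15.2%) and 2R the highest (20.8%). The cause was not tested beyond these values. For the centromere comparison, 3 bins of 2 Mb, a wider stretch of 6 Mb per arm, gave -1.90 percentage points (permutation p = 0.23) and peaks per Mb gave -11.6 (permutation p = 0.18), both past the threshold no longer. Added after seeing the data, 6 bins of 1 Mb missed it too (-2.28, permutation p = 0.13), so the wider stretch alone ended the call, and bins 3 to 5 alone reversed the sign (0.48). The cause for peaks per Mb was not tested. By construction, the upper 50% and 25% of scores left 7172 and 3582 peaks, with median widths of 1786 and 2818 bp and median scores of 79.0 and 135, and merging at 500 bp left 8325 peaks with a median width of 1465 bp. The coverage of chromosome 4 relative to the large arms was 0.34 in the upper 25% of scores, against 0.55 in the full list; the cause was not tested. The depth of the libraries is unknown, so what it limits cannot be stated.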

Other observations

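The values on peak-free stretches and arm ends, the leaving out of autosomal arms and the tests on Uextra were chosen after their results were seen, and the other tests here were added after the list was seen but stated before their own results, except the score and 500 bp merging alternatives, which were planned. The large arms held long stretches without any peak. There were 188 gaps of 100 kb or longer, 43 on 2L, 26 on 2R, 31 on 3L, 49 on 3R and 39 on X, against a mean of 0.016 and a maximum of 1 in the random placements. Of the 10 longest, 5 lay in the 2 bins nearest a centromere: 2L, 22473280 to 22959849 (487 kb, the longest), 2R, 19755 to 484166 (464 kb), and X, 22035568 to 22410626 (375 kb), 20532708 to 20898521 (366 kb) and 21500711 to 21846919 (346 kb). The other 5 lay further from the centromere: 2L, 16909973 to 17376670 (467 kb, the second longest) and 17748977 to 18113989 (365 kb), 2R, 15692780 to 16130872 (438 kb), 3R, 23790038 to 24150123 (360 kb), and 3L, 13507615 to 13853867 (346 kb). The longest gap in any random placement was 120 kb. These placements scatter the peaks singly, whereas the peaks of the list come in groups, which leaves longer gaps between the groups. The long gaps are therefore not evidence apart from the closeness of neighbouring peaks. They also cannot be told apart from stretches where reads could not be placed.

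Of the 5 large arms, 4 ended in a strong peak at the end away from the centromere. The last peak had a score of 327 on 2L (9.45 kb wide), 361 on 3L (21.1 kb), 335 on 3R (10.5 kb) and 242 on 2R (1.22 kb). The last peak of X was weak, with a score of 18.3 and a width of 0.68 kb. On 2L and 3L the peak begins at the first base of the arm. The treatment of multiply aligned reads is not known and the list gives no input reads. Reads from multi-copy sequence therefore cannot be told apart from enrichment at these ends.

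The coverage of X was weighed against 4 technical explanations. For a few rich megabases as the whole cause, the 3 highest X bins and the same share of autosomal bins were left out. The difference was then 3.08 percentage points (95% interval 0.11 to 5.88), against 3.36 with all bins. The interval treats correlated neighbouring bins as independent and its lower bound is only 0.11, so it does not settle this explanation. Weak peaks near the caller's threshold are argued against as the whole cause by a ratio of 1.40 in the upper 25% of scores (95% interval 1.14 to 1.70). That interval likewise treats correlated neighbouring bins as independent. Joining of close peaks was weighed on width alone. Regions joined at 1 kb had a ratio of 1.43 in median width (95% interval 1.25 to 1.56). This argues against joining across gaps of 1 kb or less as the whole cause of the wider peaks on X. Covered share after joining was not compared, and joining across longer gaps stays open. Whether low coverage of 1 autosomal arm carries the difference stays open, because without 2L it was 2.52 with an interval from -0.91 to 5.96. The sex of the larvae is unknown and the list holds no read counts, so the copy number of X in the input was not tested, and no biological explanation was tested.

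The closeness of neighbouring peaks was weighed against 2 explanations. Differences in density between megabases are argued against as the whole cause, since with peaks placed at random inside their own 1 Mb bin the observed share of gaps of 1 kb or less was still 46.0 percentage points above the placements. Splitting of broad regions by the caller is argued against as the whole cause only for splits across gaps of 500 bp or less. After peaks with such gaps were joined, 32.8% of the remaining gaps were 1 kb or shorter. This was 28.4 points above random placements with the same smallest gap. Splitting across gaps longer than 500 bp stays open, and it could leave such gaps, so splitting in general is not settled.

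The strong, narrow peaks of Uextra were noticed in the plot of score against width. Among peaks under 1000 bp wide, 28 of 138 on Uextra had a score of 200 or more, against 1 of 7804 on the large arms. The share of Uextra peaks above the 95th percentile of large-arm peaks of like width (within 10%) was 53.4% (exact 95% interval 45.0% to 61.7%). The share above the upper quartile score of the large arms was 35.6% (exact 95% interval 27.9% to 44.0%). Cutting of ordinary peaks at the ends of short sequence pieces stays open, since a strong peak cut into several pieces would be listed several times and the list does not give the ends of the pieces. Reads from multi-copy sequence cannot be told apart from enrichment, because the list gives no input reads.

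A hypothesis that the widest peaks lie near one another was not borne out. Of the 140 widest peaks of the large arms (the widest 1%), 30% had another of them within 100 kb, against a mean of 27.1% in 1000 random draws of as many peaks (permutation p = 0.53).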
